A study of Homo sapiens with 2 samples.

How the data were processed

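RNA from human fibroblasts was compared on 2 two-colour arrays, per the labels with time zero (T=0) of a serum-stimulation course in channel 1 of each and, in channel 2, unsynchronized cells on the first and unsynchronized cells with cycloheximide for 2 hours on the second. Each group therefore had 1 array. The labels name total RNA as the material and list the scanning software as unknown. Background correction, normalization between the channels and the dyes are not given in the sources used here.

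The deposited values are log2 ratios of the channels, with 9984 probes on each array and 0 missing values. The base of the logarithm was settled from the values: those that recur most often include the base 2 logarithms, to 3 decimals, of ratios of small whole numbers. A ratio of 0.75 occurred at 28 probes on the first array and 12 on the second, and a ratio of 0.667 at 24 and 14. The direction, channel 2 over channel 1, is likely and was read from the order of the channels and from the common T=0 source. No spot intensities, backgrounds or quality marks were used here, so dim spots could not be left out and signal over background is unknown. The deposited log2 ratios had medians of -0.08 without and -0.12 with cycloheximide, SDs of 0.55 and 0.59, and ranges from -8.05 to 4.22 and from -7.89 to 4.04.

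Probes were named from the GEO platform annotation, with symbols updated through Entrez Gene identifiers in an NCBI RefSeq gene table of the assembly GRCh38.p14, which was used for names only. Of the probes, 4758 had 1 gene symbol, 189 several and 5037 none, and of the first set 4755 matched the gene table by identifier. Probes with several symbols were not named. A further 2 probes were left out to protect the privacy of donors, which left 4756 probes for 4182 genes. Of these genes 3683 had 1 probe and 499 had 2 or more, up to 5. No genome build is named for the array, so no coordinates are printed.

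Each array was centred on the median of its probes, and a gene took the median over its probes. The effect of cycloheximide was the difference of the arrays per probe, second minus first, then the median over the probes of a gene, which can depart slightly from the difference of the gene medians. With 1 array per group no test was made: genes at or past 2-fold (1 log2 unit) were counted each way as a description of these arrays. The spread was the pooled SD between probes of the same gene, over 1073 probes of 499 genes. Different probes of a gene correlated weakly, with r 0.26 without cycloheximide, 0.25 with it and 0.20 for the difference, so that a value from a single probe is uncertain.

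The 25 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where stated. The lists covered mitosis, DNA replication, immediate-early transcripts, cytokines, growth factors, extracellular matrix, contractile cytoskeleton, sterol and fatty acid synthesis, quiescence, p53 targets, amino acid response, heat shock and chaperonins, endoplasmic reticulum, ribosomal proteins, translation factors, ribosome biogenesis, histones, proteasome, oxidative phosphorylation, glycolysis, interferon response and markers of keratinocytes, endothelium, leukocytes, and melanocytes with Schwann cells. Some genes belong to more than 1 list. For the 23 lists with 3 or more measured genes, the median was placed among those of 10000 random lists of as many genes, matched on the number of probes per gene, since no intensities were at hand to match on. The percentile describes these arrays and is not a p-value. In each comparison the 12 highest and 12 lowest genes with all probes on the same side of 0 were named, with the 3 highest and 3 lowest members of each list and any member of a list of up to 12 measured genes. Further genes are named where they make up a small count, and these were chosen after their values were seen.

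The alternatives were the values as deposited, thresholds of 1.5-fold and 3-fold, the mean over probes, the mean of a list in place of its median, each probe counted, only genes present on both arrays, only genes with 2 or more agreeing probes, both arrays scaled to the same median absolute deviation, Spearman correlation and removal of the most extreme 1% of values at each end. Another alternative was chosen after seeing the data. Values drifted with probe number at a period of 51, in each of 4 equal blocks of the numbers, and place within such rows held 18.1% of the variance on the first array, 8.9% on the second and 10.6% of their difference, against at most 2.86%, 2.66% and 2.56% after shuffling (values limited to 2 log2 units either way). Row and column medians within blocks were subtracted for that alternative. The layout was inferred from the period of the drift and is not stated in the labels.

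The correlation of the arrays was set against 100 simulated pairs of unchanged samples with a shared reference, each sample with a noise SD of 0.26, taken from the probe SD of the difference. It was also set against 100 sets of unchanged genes with the probe scatter of both arrays and its covariance between them of 0.148, a simulation chosen after seeing the data. The counting was tested on simulated data made with normal noise at the probe SD of each comparison and 200 changed genes. Wider tails were not simulated, so the shares of unchanged genes past 2-fold given in the results may be too low. Of 50 genes each with true log2 changes of 0.5, 1, 1.5 and 2, the shares past 2-fold were 22.0%, 50.0%, 90.0% and 96.0% without cycloheximide, 18.0%, 50.0%, 84.0% and 98.0% with it, and 12.0%, 52.0%, 90.0% and 100.0% for the difference. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.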

Results

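The series holds 2 control arrays for a serum-stimulation course in human fibroblasts, the connective tissue cells that make collagen and start to divide when serum is given back to resting cultures. Each was a 2-colour array, on which RNA from 2 sources is compared on the same spots. Channel 1 held RNA from time zero of the course (T=0) on both arrays. Channel 2 held RNA from unsynchronized fibroblasts on the first array and from unsynchronized fibroblasts kept for 2 hours with cycloheximide, an inhibitor of protein synthesis, on the second. There was 1 array per group, so no difference below has a replicate check and no p-value was computed. The values are log2 ratios, read here as channel 2 over channel 1. This direction is likely rather than settled: it rests on the order of the channels and on T=0 being common to both arrays, since no dye is named. If T=0 cells were resting, the lists of mitosis and DNA replication genes argue against the opposite direction. Their medians were 1.09 and 0.91 on the first array and 1.04 and 0.92 on the second. The opposite direction would place these genes higher in resting than in unsynchronized cells. Their high values below are thus no separate check of it. With the opposite direction every sign below would turn, and the numbers and shares of higher and lower genes would change places. The arrays held 9984 probes each, and 4182 genes were named from 4756 of them. The error given is the pooled SD between different probes of a gene, over the 499 genes with 2 or more probes. It is a spread within an array and not a replicate error. It was 0.45 log2 units (1.37-fold) for unsynchronized cells, 0.48 (1.39-fold) with cycloheximide and 0.37 (1.29-fold) for the difference of the arrays. The number of arrays limits the precision of every value.

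The first comparison asks how freely cycling fibroblasts differ from those at the start of the serum course. Transcripts of cell division and DNA replication stood highest in unsynchronized cells. CCNB1 (Entrez Gene 891), the cyclin that drives entry into mitosis, had a log2 ratio of 2.64, or 6.25-fold over T=0. RRM2 (Entrez Gene 6241), the ribonucleotide reductase subunit that supplies deoxynucleotides, stood at 2.28, MAD2L1, of the spindle checkpoint, at 2.17, AURKA, a mitotic kinase, at 2.12 and MKI67, the proliferation antigen, at 2.08. The other genes among the 12 highest were TPX2 (1.82), GMNN (1.80), CKAP2 (1.72), MYO10 (1.72), HAT1 (1.69), CDK1 (1.68) and ID3 (2.49), an inhibitor of helix-loop-helix transcription factors. Each of these genes rests on 1 probe. Where a probe of a gene with several probes was 2-fold higher (30 ordered pairs), the second probe lay above 0 in 19 and was 2-fold higher too in 6. On the low side (35 ordered pairs) the second probe lay below 0 in 25 and was 2-fold lower too in 2. The 12 lowest genes ran from HPCAL4 at -1.89 to GASK1B at -1.59. They took in IDI1 (-1.73), an enzyme of isoprenoid synthesis, LOX (-1.60), which cross-links collagen and elastin, and KIT (-1.67), a receptor tyrosine kinase. SSR1 (-1.84), GUCY1A1 (-1.83), PLPP1 (-1.75), FAT4 (-1.74), ARHGAP20 (-1.68), FTO (-1.67) and DBX2 (-1.65) made up the rest. On the second array, with cycloheximide, HPCAL4 (-0.05), SSR1 (-0.19), PLPP1 (0.02), FTO (-0.24) and DBX2 (0.41) were not low to this degree. The others ran there from GUCY1A1 at -0.635 to KIT at -1.88. HPCAL4 rests on a pair of probes at -3.39 and -0.40, and GASK1B on probes at -1.47 and -1.71.

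Of 19 measured genes of mitosis and the G2/M transition, 10 were at least 2-fold higher in unsynchronized cells, 0 were 2-fold lower and 9 lay within 2-fold. The list median of 1.09 stood at percentile 100 of 10000 random lists of as many genes, whose central 95% ran from -0.26 to 0.30. Its lowest members were WEE1 (-0.11), FOXM1 (-0.51) and CCNF (-0.64). Of 14 genes of DNA replication and the G1/S transition, 6 were 2-fold higher and 0 lower, with a median of 0.91 at percentile 100. RRM2, GMNN and FEN1 (1.61) led that list, while RFC3 (-0.17) and CHAF1A (-0.58) stood below T=0. Protein folding and turnover genes were also on the higher side. The 10 cytosolic heat shock and chaperonin genes had a median of 0.84 (percentile 99.99), led by HSP90AA1 at 1.60, and of 0.49 (percentile 99.92) with position medians removed. The 12 proteasome genes had a median of 0.56 (percentile 99.83), led by PSMC1 at 1.01 and PSME3 at 0.98. Only 1 gene of each of these lists reached 2-fold. Immediate-early and otherwise labile transcripts had a median of 0.33 over 18 genes (percentile 98.7). The 4 of them past 2-fold were ID3, ZFP36L1 (1.57), KLF10 (1.02) and JUNB (2.01-fold). After medians by position on the array were removed, KLF10 stood at 0.41, JUNB at 0.56, HSP90AA1 at 0.69 and PSMC1 at 0.78, under 2-fold. The chaperone list then held 1 other gene 2-fold higher and the proteasome list 0.

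The lists of cell-cycle inhibitors and quiescence and of extracellular matrix had medians below the central 95% of random lists. The quiescence list had a median of -0.30 over 20 genes (percentile 0.62), with TXNIP (-1.21), a thioredoxin-binding protein that restrains glucose uptake, and CDKN1C (-1.01), a cyclin-dependent kinase inhibitor, past 2-fold. CDKN1C stood at -0.58 once position medians were removed. The 23 matrix genes had a median of -0.30 (percentile 0.71). LOX, FMOD (-1.38) and LUM (-1.25), the latter pair being proteoglycans that bind collagen fibrils, were 2-fold lower, while NID1 (0.996), PLOD2 (0.83) and COL6A3 (0.80) were the highest members. The matrix median was -0.19, at percentile 2.74, with position medians removed. Of 15 genes of sterol and fatty acid synthesis, 5 were 2-fold lower and 0 higher. These were IDI1, SCD (-1.35), SC5D (-1.21), DHCR7 (-1.06) and FADS2 (-1.03, or -0.84 with position medians removed). The other 10 lay within 2-fold, with ACLY (0.52), NPC1 (0.49) and EBP (0.47) highest, so that the list median was -0.20 (percentile 6.22), against -0.33 (percentile 0.32) with position medians removed. The mean of the list was -0.40 (percentile 0.06).

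Translation factors had a median of 0.35 over 19 genes (percentile 99.2), with EIF1AX at 1.14 (0.83 with position medians removed), and the 4 measured genes of ribosome biogenesis a median of 0.87 (percentile 99.94), with RRS1 at 1.38. Both depended on position, with medians of 0.14 (percentile 91.0) and 0.39 (percentile 96.7) after its removal. Oxidative phosphorylation (7 genes) had a median of 0.42 at percentile 95.8. The cytokine list of 6 genes had a median of -0.39 (percentile 3.23, and 0.91 with position medians removed) but a mean of -0.04 (percentile 36.8), and CXCL12, a chemokine of stromal cells, stood at 1.28 on 2 probes. Medians inside the central 95% of random lists were found for growth factors and their receptors (0.11, or -0.20 with position medians removed, 9 genes), contractile cytoskeleton (0.21, 10 genes), p53 targets (-0.14, 8 genes), amino acid response and tRNA synthetases (0.10, with a mean of -0.01, 16 genes), histones (-0.20, 4 genes) and interferon response (0.13, or -0.003 with position medians removed, 6 genes). That removal brought the medians of contractile cytoskeleton and of amino acid response to 0.04, of p53 targets to -0.05 and of histones to -0.01. In the contractile list ACTG1 (1.14) and CFL1 just passed 2-fold and stood at 0.77 and 0.51 with position medians removed. The endoplasmic reticulum list of 11 genes had a median of 0.29 and a mean of -0.04, pulled below 0 by SSR1, and its median was 0.00 (percentile 49.4) with position medians removed. RPL37A, the only measured gene of the ribosomal protein list, stood at 0.45 and PFKFB3, the only gene of the glycolysis list, at 0.48. Markers of other cell types that a fibroblast culture could hold stayed within 2-fold of T=0. Their medians were -0.03 for keratinocytes (4 genes), -0.14 for endothelium (6 genes), -0.11 for leukocytes (5 genes) and 0.17 for melanocytes and Schwann cells (3 genes).

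Over all 4182 genes, 140 were at least 2-fold higher in unsynchronized cells and 78 at least 2-fold lower, so that 64.2% of the genes past 2-fold were higher. With the values as deposited, before centring on the array median, the numbers were 101 and 112 (47.4% higher), and with position medians removed 75 and 76 (49.7% higher), of which 61 and 48 were shared with the main sets. In unchanged genes simulated with normal noise at the probe SD of this array, 96 of 3982 (2.41%) passed 2-fold. Of the measured genes 218 of 4182 did so either way, and part of this number could come from such noise.

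**Figure D1:**
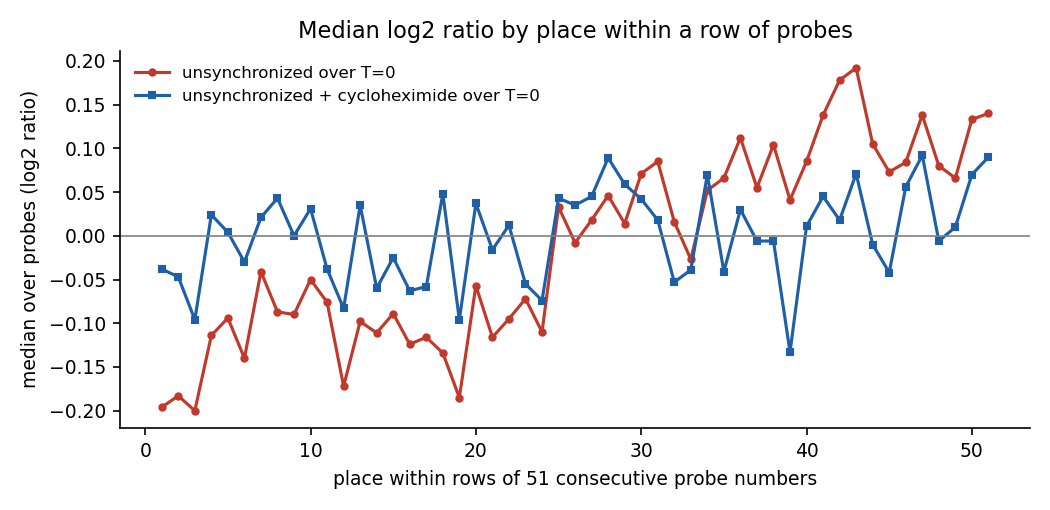
Median log2 ratio over probes (vertical axis) at each place within rows of 51 consecutive probe numbers (horizontal axis), for the array of unsynchronized cells (red circles) and the array with cycloheximide (blue squares). On the first array the medians run from -0.20 at place 3 to 0.19 at place 43, and on the second from -0.13 to 0.09.

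The second array compared unsynchronized cells kept with cycloheximide with the same T=0 RNA. DUSP1 (Entrez Gene 1843), a phosphatase that inactivates MAP kinases, stood at a log2 ratio of 3.45, or 11.0-fold over T=0, and ID3 at 3.22. JUNB (2.72) and ETS2 (2.15), both transcription factors, KLF10 (2.22), a zinc finger repressor induced by TGF-beta, and MCL1 (2.12), a short-lived survival protein measured on probes at 2.39 and 1.84, were also among the 12 highest. UNC79 (3.55), DNPH1 (3.51), STAMBPL1 (2.76), TRIM3 (2.23), CCNB1 (2.22) and MKI67 (2.13) completed them. The lowest was PARD6G, a cell polarity protein, at -3.94, or 15.4-fold below T=0, followed by CNOT6 (-2.37), a subunit of the main mRNA deadenylase complex, EPM2A-DT (-2.34) and ACP2 (-2.02), a lysosomal phosphatase. SCD (-1.96), the desaturase that makes monounsaturated fatty acids, RDH10 (-1.93), KIT (-1.88), SLC25A15 (-1.87), SLC8A2 (-1.73), SUSD4 (-1.70), NUS1 (-1.60) and RNASE1 (-1.54) followed. Apart from MCL1, each of these genes rests on 1 probe. Of 45 ordered pairs with a probe 2-fold higher the second lay above 0 in 30 and was 2-fold higher too in 12, and of 37 with a probe 2-fold lower it lay below 0 in 25 and was 2-fold lower too in 4.

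Division and replication genes stood at levels close to those without the inhibitor. The mitosis list had a median of 1.04 (percentile 100), with 10 of 19 genes 2-fold higher and 0 lower, and the replication list a median of 0.92 (percentile 100), with 6 of 14 higher and 0 lower. The immediate-early list had a median of 0.74 (percentile 100), and 8 of its 18 genes were 2-fold higher, against 0 lower; NR4A2 (-0.80), DUSP4 (-0.46) and HES1 (-0.31) were its lowest members. The proteasome list had a median of 0.43 (percentile 98.7), led by PSME4 at 1.37. The chaperone list had a median of 0.65 (percentile 99.86), but of 0.22, inside the random range at percentile 90.1, with position medians removed. Translation factors had a median of 0.32 (percentile 98.0, and 97.0 with position medians removed), with ETF1 (1.29) and EIF1AX (1.01, or 0.85 with position medians removed) past 2-fold. The 4 histone genes had a median of 0.56 (percentile 96.2, and 99.3 with position medians removed), with H2AC6 at 1.56. Matrix genes had a median of -0.27 (percentile 0.68), with LUM (-1.38) and FMOD (-1.19) past 2-fold on the low side and PLOD2 (1.02) on the high side. Removing position medians gave a matrix median of -0.09, at percentile 14.9, and PLOD2 at 0.62, while 5 matrix genes in place of 2 were then 2-fold lower: LUM (-1.72), FMOD (-1.22), COL1A1 (-1.11), COL6A1 (-1.10) and FBLN1 (-1.01). In the sterol and fatty acid list 4 of 15 genes were 2-fold lower, namely SCD, FADS2 (-1.42), SC5D (-1.13) and DHCR7 (-1.06), around a median of -0.06 (percentile 27.3). The mean of that list was -0.31 (percentile 0.49), and its median -0.19 (percentile 5.18) with position medians removed.

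The quiescence list had a median of 0.09 (percentile 66.0), with TXNIP (1.62) and CITED2 (1.46) 2-fold higher and CDKN1C (-1.35, or -0.92 with position medians removed) lower. Among 8 p53 targets PMAIP1 (1.81) and PLK2 (1.70) were 2-fold higher and ZMAT3 (-1.30) lower, around a median of 0.10. The remaining medians lay inside the central 95% of random lists: cytokines 0.25, growth factors 0.20, contractile cytoskeleton 0.33, amino acid response and tRNA synthetases -0.15, endoplasmic reticulum 0.33, ribosome biogenesis 0.47, oxidative phosphorylation 0.42 and interferon response 0.05 (-0.006 with position medians removed). That removal also lowered the medians of growth factors to 0.03, endoplasmic reticulum to 0.19 and ribosome biogenesis to 0.14. RPL37A stood at 0.39 and PFKFB3 at 0.89. The other cell types had medians of -0.11 for keratinocytes, -0.19 for endothelium, 0.08 for leukocytes (mean -0.02, and median -0.07 with position medians removed) and 0.18 for melanocytes and Schwann cells (mean -0.11), with 0 markers past 2-fold. On this array 156 genes were at least 2-fold higher than T=0 and 83 at least 2-fold lower (65.3% higher). With the values as deposited the numbers were 99 and 130 (43.2% higher), since centring moved this array by 0.12. Removal of position medians gave 140 and 72, of which 101 and 50 were shared with the main sets. Of 3982 unchanged genes simulated with normal noise at the probe SD of this array, 131 (3.29%) passed 2-fold. Among the measured genes 239 of 4182 did so either way, and part of this number could come from such noise.

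**Figure D2:**
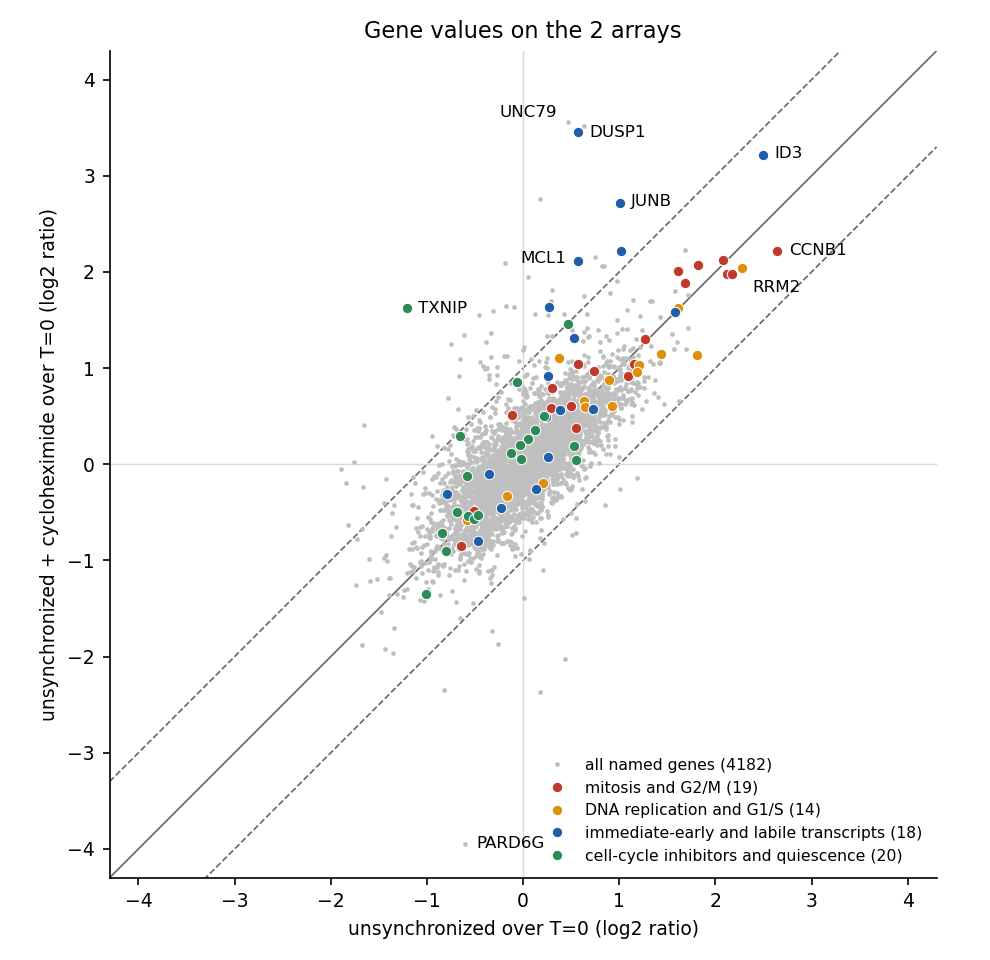
Log2 ratio of each named gene in unsynchronized cells (horizontal axis) and in unsynchronized cells with cycloheximide (vertical axis), both over T=0, for 4182 genes in grey and 4 gene lists in colour. The solid line marks equal values and the dashed lines a 2-fold difference between the arrays. DUSP1 (0.57 and 3.45) and TXNIP (-1.21 and 1.62) lie above the upper dashed line, while CCNB1 (2.64 and 2.22) lies between the lines.

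The difference of the arrays is read here as the effect of cycloheximide in unsynchronized cells, since the T=0 RNA is common to both. With 1 array per group it also holds every difference between the hybridizations, including noise of the T=0 channel on each array. Inhibitors of protein synthesis are used in serum studies to find transcripts whose levels do not need newly made protein, and they also stabilize many short-lived mRNAs. DUSP1 was 2.88 log2 units (7.36-fold) higher with cycloheximide and TXNIP (Entrez Gene 10628) 2.84 (7.13-fold). ARRDC3 (2.00), an arrestin-domain protein related to TXNIP, RGS4 (2.28), which switches off G protein signals, and NEDD9 (2.01), a focal adhesion scaffold with probes at 2.17 and 1.85, were also among the 12 highest. UNC79 (3.08), DNPH1 (2.88), STAMBPL1 (2.58), DBX2 (2.06), GJB1 (1.96), a gap junction protein, PDE7B (1.91), a cyclic AMP phosphodiesterase, and FILIP1L (1.89) completed them. DBX2 stood at -1.65 without and 0.41 with cycloheximide, so its difference lies mainly in its low value on the first array. On the low side PARD6G (-3.34, 10.1-fold), CNOT6 (-2.54) and ACP2 (-2.46) led, followed by SLC25A15 (-1.61), the mitochondrial ornithine carrier, EPM2A-DT (-1.53), SLC8A2 (-1.41), TAFAZZIN (-1.40), COL13A1 (-1.32), IDE (-1.31), the insulin-degrading enzyme, HLMR1 (-1.28), HDHD5 (-1.27) and LARP4B (-1.27). All 12 of the lowest genes rest on 1 probe each, and so do the 12 highest apart from NEDD9. Where a probe of a gene with several probes was 2-fold lower (6 ordered pairs), the second lay below 0 in 2 and was 2-fold lower too in 0, against 15 above 0 and 6 higher too of 23 pairs on the high side.

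The immediate-early list had a median difference of 0.37 (percentile 99.97), and 5 of its 18 genes were 2-fold higher with cycloheximide and 0 lower. The 5 were DUSP1, JUNB (1.71), MCL1 (1.55), FOSL2 (1.37), a partner of JUN proteins, and KLF10 (1.19). The list was not uniform: ID1 (-0.39), NR4A2 (-0.34) and DUSP4 (-0.23) were its lowest members, and the pair of probes of DUSP6, a gene chosen after its values were seen, disagreed at 1.64 and -0.33. Of the 4 histone genes, H2AC6 (1.44) and H2BC12 (1.25) were 2-fold higher, H2AZ2 stood at 0.58 and H2AJ at -0.10, with a median of 0.92 (percentile 99.97), or 0.58 (percentile 99.67) with position medians removed. Among 8 p53 targets PMAIP1 (1.52), a pro-apoptotic BCL2 family protein, and PLK2 (1.41) were 2-fold higher and CDKN1A, the cyclin-dependent kinase inhibitor shared with the quiescence list, stood at 0.92. The median of that list was 0.14 (percentile 89.0), against 0.32 (percentile 99.5) with position medians removed, and its mean was 0.46 (percentile 99.6). The quiescence list had a median of 0.20 (percentile 99.2), or 0.10 (percentile 90.7) with position medians removed, with TXNIP past 2-fold and CITED2 (0.99) and KLF9 (0.96) just under it. SOD2, the manganese superoxide dismutase induced by inflammatory signals, was 1.70 higher, the only gene of the 6 in the cytokine list past 2-fold, where CXCL12 stood at -0.62 from probes at 0.02 and -1.25.

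Division genes differed little between the arrays: the mitosis list had a median difference of 0.05 (percentile 74.5) and the replication list -0.16 (percentile 7.11), with 0 genes of either past 2-fold. WEE1 (0.63) and CCNB1 (-0.42) were the extremes of the first list, and MCM2 (0.73) and GMNN (-0.67) those of the second. With position medians removed CCNB1 stood at -0.22 and GMNN at -0.14, the latter then above RRM2 at -0.36. The 4 ribosome biogenesis genes all stood lower with cycloheximide, with a median of -0.35 (percentile 1.70), or -0.23 (percentile 5.64) with position medians removed, from NOP56 at -0.60 to POLR1D at -0.14. The chaperone list had a median of -0.22 (percentile 2.68), with HSPA1L lowest at -0.76. Its percentile was 1.06 with both arrays at the same median absolute deviation, but 18.3, with a median of -0.08, once position medians were removed. In the sterol list, with a median of 0.15 (percentile 94.6), or -0.21 over its 3 genes with 2 or more agreeing probes, IDI1 stood at 0.95 and SCD at -0.61. With position medians removed IDI1 stood at 0.49 and SCD at -0.62. SSR1 (1.65, from -1.84 without and -0.19 with cycloheximide) was the only endoplasmic reticulum gene past 2-fold. Its list had a median of 0.14, or -0.01 with position medians removed. The sign also turned on that removal for contractile cytoskeleton (0.05) and oxidative phosphorylation (0.04). Medians of the remaining lists lay inside the central 95% of random lists: cytokines 0.17, growth factors 0.06, matrix -0.03, contractile cytoskeleton -0.03 (mean 0.01), amino acid response and tRNA synthetases -0.10, translation factors 0.06, proteasome -0.14, oxidative phosphorylation -0.10, interferon response -0.24, keratinocytes -0.01, endothelium -0.12, leukocytes 0.02, and melanocytes and Schwann cells -0.19. RPL37A differed by -0.05 and PFKFB3 by 0.41.

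**Figure D3:**
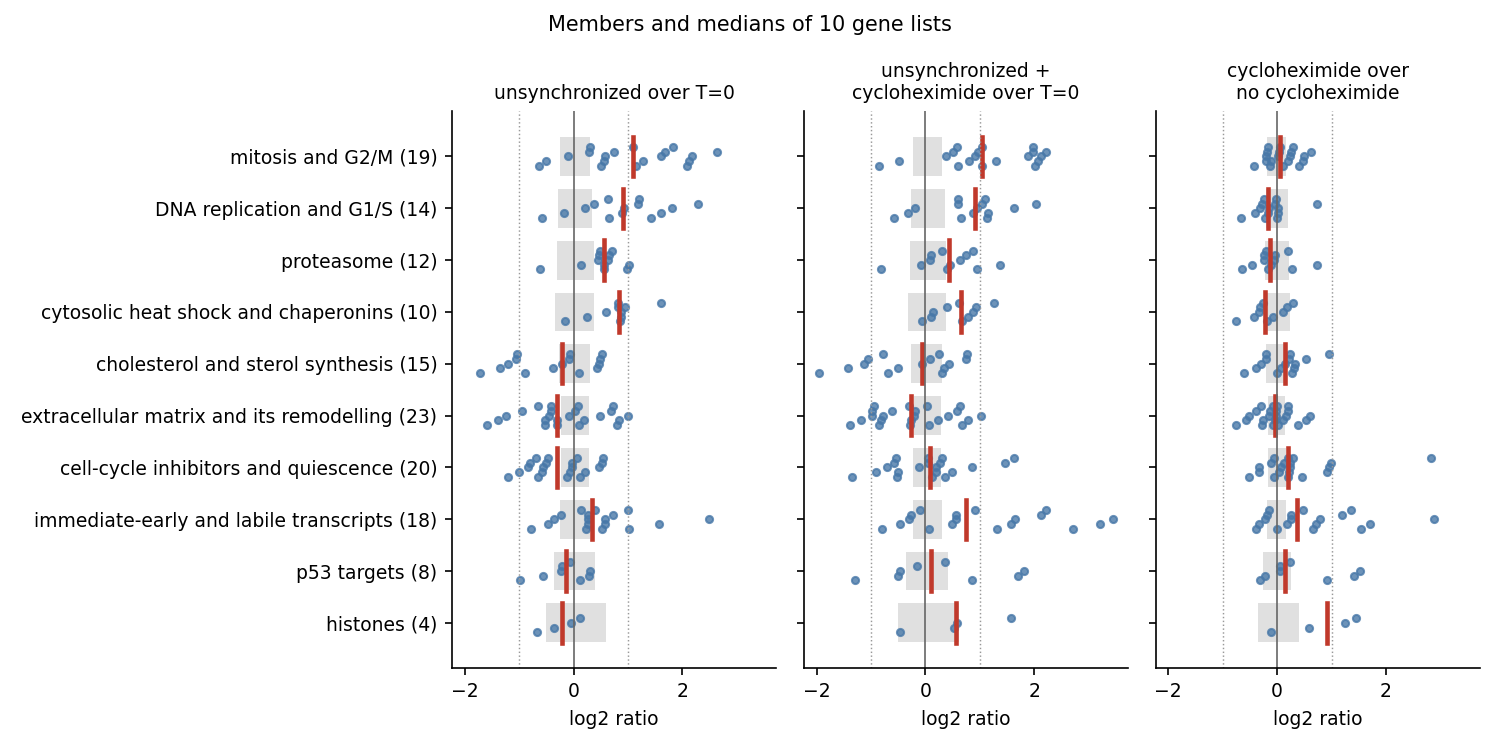
Log2 ratios (horizontal axes) of the measured members (blue points) of 10 gene lists (rows, with the number of measured genes) in the 3 comparisons, with the list median (red bar) and the central 95% of medians of 10000 random lists of the same size (grey). Dotted lines mark 2-fold. The mitosis median is 1.09 and 1.04 over T=0 and 0.05 for the effect of cycloheximide, while the immediate-early median is 0.33, 0.74 and 0.37.

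With cycloheximide 67 genes were at least 2-fold higher and 18 at least 2-fold lower than without it, so that 78.8% of the genes past 2-fold were higher. With the values as deposited these numbers were 61 and 22, and after removal of position medians 58 and 16, of which 53 and 13 were shared with the main sets. In unchanged genes simulated with normal noise at the probe SD of the difference, 30 of 3982 (0.75%) passed 2-fold, against 85 of 4182 measured. Of 50 genes simulated with a true change of 2-fold 52.0% did. Wider tails of the probe scatter were left out, so the first share may be too low. Among 270 genes with 2 or more probes on the same side of 0, 5 were 2-fold higher, namely NEDD9, HPCAL4, TSC22D1, MCL1 and SV2B, and 0 lower. The probes stood at 2.98 and 0.70 for HPCAL4 and at 2.22 and 0.01 for SV2B, so that in each the second probe lay under 2-fold.

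Across the 4182 genes the arrays correlated with a Pearson r of 0.724 and a Spearman rho of 0.738. Genes are not independent replicates, and both arrays share the T=0 RNA. Unchanged samples simulated against a shared reference, with noise taken from the difference of the arrays, gave an r of 0.501. That value is set by giving the samples and the reference the same noise. That noise leaves out scatter that probes share between the arrays. In a second simulation, chosen after the result was seen, unchanged genes had the probe scatter of both arrays, its shared part included, and r was 0.685. This r follows from the probe scatter put in, so both simulations are baselines and not tests. The covariance was 0.201, against 0.069 and 0.140 in these simulations, differences of 0.132 and 0.061. Higher than T=0 by 2-fold on both arrays were 65 genes, where independent lists would share 5.22 and the simulations gave 1.23 and 15.97. Lower on both were 33, against 1.55 for independent lists and 1.02 and 16.4 in the simulations. The reference could not be split, so part of this excess may come from it. The only gene 2-fold below T=0 without cycloheximide and 2-fold above it with cycloheximide was TXNIP, and 0 genes were placed the opposite way.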

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

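The tests of position on the array for both patterns below, and of centring for unsynchronized cells, were chosen only after the result was seen. TXNIP was the only gene at least 2-fold below T=0 in unsynchronized cells (-1.21) and at least 2-fold above it with cycloheximide (1.62), a difference of 2.84 log2 units. It was picked out because the groups lie on opposite sides of T=0. The difference was not tested, as there was 1 array per group and 1 TXNIP probe. With position medians removed the values were -1.18 and 1.40, and the difference 2.58.

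More genes were raised than lowered by 2-fold with cycloheximide (67 and 18, a ratio of 3.72). With position medians removed the ratio was 3.63, which argues against position as the whole cause. Without centring it was 2.77, but this follows from a small shift of every gene alike and does not decide whether centring is a cause. Scaling both arrays to the same median absolute deviation moved the counts over T=0 to 155 and 87 without and 138 and 74 with cycloheximide. The ratio of raised over lowered genes was then 3.58. Such scaling acts alike on values above and below 0, so it does not decide whether a wider spread of the cycloheximide array plays a part. Differences in labelling or spot quality between the hybridizations were not tested and stay open. An effect of the block of protein synthesis is also open, could not be tested with 1 array per group, and would turn in sign if the ratios ran the other way.

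More genes were also higher than lower by 2-fold in unsynchronized cells (140 and 78, a ratio of 1.80). The ratio was 0.987 with position medians removed and 0.714 among genes with 2 or more agreeing probes, a value that rests on only 5 and 7 genes. The excess of higher genes could therefore come from position. The 5 and 7 genes are too few to decide whether the scatter of single probes is a cause. The ratio of 0.902 with the values as deposited follows from a shift of every gene alike and does not decide whether centring is a cause. A true excess in cycling cells stays open and was not tested.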

How the results depend on the processing

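The removal of position medians was chosen only after the results were seen, and the other alternatives were planned. Counts below are higher then lower than T=0 for unsynchronized cells, the same with cycloheximide, then with cycloheximide over without. At 1.5-fold they were 551 and 419, 595 and 438, and 256 and 138; at 3-fold 17 and 12, 40 and 11, and 22 and 4 (PARD6G, CNOT6, ACP2, SLC25A15). These follow from the thresholds. Only genes with 2 or more agreeing probes gave 5 (ADHFE1, CENPF, CXCL12, METTL9, RFLNB) and 7 of 271, 9 and 4 (DHCR7, GASK1B, SESN3, ZMAT3) of 283, and 5 (NEDD9, HPCAL4, TSC22D1, MCL1, SV2B) and 0 of 270, as fewer genes were counted; 0 of the 3 list medians left to place then fell outside the central 95% of random lists, against 20 of 69 in the main setting. With the values as deposited the cycloheximide array gave 99 and 130 in place of 156 and 83, by the shift of its zero. After removal of position medians 75 genes in place of 140 were higher in unsynchronized cells, the correlation of the arrays was 0.705 in place of 0.724, and 16 of 69 list medians lay outside; the cause was not tested. Spearman's rho was 0.738. The other 42 checks of counts, correlation and number of lists stayed within 1.5 times the main count or the bootstrap SD of 0.011. Of the list medians recomputed, 391 stayed within the SD of random lists and 26 moved further, 16 of them with position medians removed, 8 with the mean of a list and 2 with 2 or more agreeing probes, and 0 of those outside the random range changed sign. Of the leading genes 5 moved by more than the probe SD, all with position medians removed: GMNN, GUCY1A1, MKI67 and RRM2 without and KLF10 with cycloheximide. Counting only genes on both arrays changed 0 counts, since no value was missing. Thus 7 of the 42 checks and 69 of the 391 list medians restate the main setting. Another 69 list medians used the mean over probes, which equals the median for every gene with 1 or 2 probes. No intensities were used, so what dim signal limits is unknown.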

Other observations

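The test of position on the array was planned before its result was seen; the single genes named first below were picked after their values were seen, with no list or test behind them, and stand for no group. Outside the lists and leading genes, CCNL1, a cyclin tied to RNA splicing, differed by 1.83 with cycloheximide, BCL6, a transcriptional repressor, by 1.73, RND3, a GTPase that opposes contraction, by 1.75 and TSC22D1, on 2 probes, by 1.66. SLBP, the protein that binds the stem-loop of replication-dependent histone mRNAs, differed by 1.21. After removal of position medians these 5 genes stayed past 2-fold, from 1.29 for SLBP to 1.89 for CCNL1. All but TSC22D1 rest on 1 probe. In unsynchronized cells DEPDC1B stood at 1.62 over T=0 and differed by -0.96 with cycloheximide, and ESPL1, the protease that parts sister chromatids, stood at 1.19. WNT5A, a secreted signal, stood at -1.40 and OGN, a small matrix proteoglycan, at -1.41.

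Probes without a gene symbol passed 2-fold somewhat more often than named probes: 6.35% against 5.45% in unsynchronized cells, 7.66% against 6.18% with cycloheximide, and 3.20% against 2.23% for the difference, where 114 of the 5037 were higher and 47 lower.

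Different probes of a gene disagreed in the same way on both arrays: their deviations from the gene mean correlated with an r of 0.684. After removal of position medians the r was 0.652, which argues against position as the whole cause. Cross-hybridization, probes named for the wrong gene and probes of different transcripts could each give such a pattern. So could uneven reading of the shared T=0 RNA by different probes. None of these was tested. No biological explanation was tested.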
